A study of Mus musculus with 16 samples.

How the data were processed

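The series holds 16 Affymetrix arrays of mouse wound tissue, 4 in each of 4 groups (unstressed and stressed, day 6 and day 14). Per the labels, the replicates of a group are numbered 1 to 4, and the design text gives 4 mice per group and time point. Per the series design text, each gene was represented by 20 pairs of perfectly matched and mismatched oligonucleotides, and the authors processed the intensity files with GeneSpring GX 11.0. The background correction, summarization and between-array normalization are not given in the sources used here. The deposited values are on a log scale and were read as log2. They were centred per probe set by the authors before deposit, as the values show: rows lie around 0 on either side. The reference of the centring is unknown, because only 6.3% of probe sets have a median over these arrays within 0.001 of 0, and 51.3% hold a pair of equal and opposite values (within 2e-06). It cancels in differences between arrays. The largest range of a probe set over the arrays, 10.08, exceeds the 4.82 that log10 of a 16-bit scan allows, so the values are not log10, while natural logs stay possible and would make each log2 difference larger than printed. Because of the centring, no absolute level, background or detection could be judged, and log2(value + 16), an alternative fixed in advance, was not run.

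Probe sets were named with the annotation table of the platform. Of 45101 probe sets, 34945 had 1 gene symbol, 932 had several and 9224 had none in that table, 64 of the rows being Affymetrix controls. Probe sets with several symbols or none were left out of the tests, 0 symbols changed through their Entrez identifier, and no gene coordinates are given. A gene was represented by its probe set with the largest interquartile range over the 16 arrays, the rule fixed for a centred table, which left 18193 genes, 9010 of them with more than 1 probe set. No filter on low values was applied. Focal adhesion kinase and several other genes of the lists are not analysed here.

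Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the group means of all 16 arrays, which share 1 estimate of the spread, and 5 contrasts were tested two-sided: the loading effect at each day, the difference between these effects, and the time effect in unstressed and in stressed wounds. P-values were adjusted with the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Gene lists (13 pathways, 18 cell types and 1 control list of ribosomal proteins, 32 in all) were tested with limma's camera at its preset correlation of 0.01, adjusted over the 32 lists. Some genes belong to more than 1 list, such as Csf1r to the macrophage and cytokine lists, so called lists are not independent. No camera call in the 5 comparisons held with an estimated correlation. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Controls, plots and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

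The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest positive and 8 largest negative log2 differences among genes past the threshold whose groups did not overlap (5 each way for the difference between days, with no overlap condition), up to 4 members of each list described, and Ptk2, Ccl2, Acta2, Col1a1 and Col3a1 for loading. Clones and predicted genes without an official symbol were skipped. Outside this rule, Tnnc1 at day 14, Hoxc10 at day 14 and the genes of the closing section that the report does not name were chosen after their values were seen.

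The fit was tested on simulated data in which 100 genes changed by 1 and 100 by 2 on the log2 scale among 18193. It recovered 67% and 95% of them for the day 6 loading effect, 69% and 96% for day 14, 52% and 87% for the difference between days, 75% and 93% for time in unstressed and 74% and 93% for time in stressed wounds, with 8, 7, 8, 10 and 3 false calls. The simulated noise was normal, independent between genes, and for each gene of the same SD in all groups. It held no correlation between genes, no spread that differs between days and no classes of arrays. These rates therefore check the code and do not measure errors on the real arrays. Replicates were compared before averaging, and the SD of the differences between replicates of a group was at least 0.237 on the log2 scale, so no 2 replicates of a group held identical values. Same-numbered arrays were checked for shared deviations from their group means. At day 14 the correlations of the 4 pairs of stressed and unstressed arrays were 0.30, 0.18, 0.27 and 0.19, all above 0.1. The arrays of a pair lie in the same Xist class, which alone could give such correlations. Unstressed replicate 2 correlated best with stressed replicate 1. The main fit holds no pairs. At day 14 the numbers were used as pairs only in the replicate blocks, in splits of the arrays and in a permutation test, and a pairing beyond the class is not shown. At day 6 the correlations were -0.13, -0.41, -0.18 and 0.00, so the numbers only name these samples. Nor did all same-numbered arrays of the 2 days correlate above 0.1. The alternatives tried, fixed in advance, were another normalization, array centring, a filter on the interquartile range of the lowest 40% of genes, the mean of or each of a gene's probe sets, only the groups compared, replicate blocks, eBayes with trend and robust options, array weights, a 2-fold limit, leaving out each array, and fry or camera with an estimated correlation. Chosen after the data were seen were the fits with Xist as a block, with only arrays of 1 Xist class, without 3 arrays with low 5' signal of control genes, and with the 5' minus 3' difference as a covariate.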

Results

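RNA from healing skin wounds of wild-type mice was measured on 16 Affymetrix GeneChip arrays. The wounds had either been left without mechanical load (unstressed) or been loaded (stressed), and tissue was taken on day 6, after 48 hours of loading, or on day 14, after 10 days of loading. Each of the 4 groups held 4 arrays, and the design text assigns 4 mice to each group and time point. Values are log2 signals centred per probe set, so 0 is no absolute level and only differences between arrays can be read. The files do not state the log base; it was read as 2, and natural logs could not be excluded. The number of arrays limits the precision. The series title names focal adhesion kinase, fibrosis and chemokines, and the comparisons ask how loading changed the transcripts of the wound at each day. The gene for focal adhesion kinase, Ptk2, is not analysed here.

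In stressed wounds at day 6, only 10 of 18193 genes passed an adjusted p of 0.05 in limma, 6 of them higher and 4 lower than in unstressed wounds. Defb8, which encodes a beta-defensin, rose by 4.80 on the log2 scale (SE 0.59, adjusted p = 0.008), from -0.21 ± 0.31 to 4.60 ± 1.81 (SD, n = 4). Comp, which encodes cartilage oligomeric matrix protein, rose by 0.96 (SE 0.14, adjusted p = 0.019). The other genes that rose were Camk4, a calcium- and calmodulin-dependent kinase (1.61), Zfpm2, a transcriptional cofactor (1.47), Glis3, a zinc finger transcription factor (1.09), and Syt13, a synaptotagmin (1.05). For Camk4, 4 of its 5 probe sets shared that direction. Of the 4 genes that fell, the homeobox gene Hoxc10 fell by 3.65 (SE 0.51, adjusted p = 0.014), from 2.89 ± 0.35 to -0.76 ± 0.05 (SD, n = 4). Gdf5, a growth factor of the bone morphogenetic protein family, fell by 1.72, the LIM homeobox gene Isl1 fell by 1.54 and Hoxa7 fell by 1.22.

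No member of the 32 gene lists fixed before the data were examined passed the threshold over all genes at day 6, but many members of several lists lay on one side. Of 39 measured genes for collagens and matrix assembly, 37 were higher in stressed wounds, the median difference was 0.71, and 11 passed when adjusted over the list alone. The smallest p-values in that list belonged to P4ha3, a collagen prolyl hydroxylase subunit (1.35, SE 0.28, adjusted p = 0.13), Fn1, fibronectin (1.38, SE 0.32, adjusted p = 0.2), Plod2, a collagen lysyl hydroxylase (1.28) and Tnc, tenascin C (1.24). The list stood apart from other genes in limma's camera test (adjusted p = 1.4e-20), but not with an estimated correlation (adjusted p = 0.24 with an estimated correlation). Fibroblast markers had a median of 0.61, with 15 of 16 genes higher and 0 past the threshold over the list alone (camera adjusted p = 1.9e-06, and adjusted p = 0.29 with an estimated correlation). Col1a2 (0.92, adjusted p = 0.4) and Pdgfra (0.81, adjusted p = 0.48) had the smallest p-values among them. Matrix proteases and inhibitors had a median of 0.46 (camera adjusted p = 9.4e-07, and adjusted p = 0.29 with an estimated correlation), with 2 genes past the threshold adjusted over the list alone. Mmp19 (1.14, adjusted p = 0.24) and Timp1 (1.44, adjusted p = 0.38) led that list.

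Of 33 chemokine genes, 25 were higher in stressed wounds at day 6, with a median of 0.31 and 2 past the threshold adjusted over the list alone (camera adjusted p = 3.9e-05, and adjusted p = 0.29 with an estimated correlation). The values were 1.02 for Ccl17 (SE 0.21, adjusted p = 0.13), 1.55 for the eosinophil attractant Ccl11 (SE 0.36, adjusted p = 0.2), 2.09 for the neutrophil attractant Cxcl1 (SE 0.67, adjusted p = 0.46) and 1.29 for the monocyte attractant Ccl2 (SE 0.46, adjusted p = 0.56). Interferon response genes had a median of 0.42, with 22 of 24 genes higher, and macrophage and monocyte markers had a median of 0.36, with 20 of 22 higher. Neither list had a member past the threshold over the list alone, and their camera calls (adjusted p = 3.2e-06 and 6.9e-05) were not kept (adjusted p = 0.4 and 0.44 with an estimated correlation). Markers of suprabasal and cornified keratinocytes lay lower, in 23 of 24 genes, with a median of -0.48 (camera adjusted p = 3.8e-06, and adjusted p = 0.29 with an estimated correlation). Among them Krt2 had a difference of -2.27 (SE 0.67, adjusted p = 0.39). Of the genes named in advance, Acta2 differed by 0.76 (SE 0.46, adjusted p = 0.9), Col3a1 by 0.45 (SE 0.33, adjusted p = 0.94) and Col1a1 by -0.02 (SE 0.46, adjusted p = 1). Camera also called mast cell, dendritic and Langerhans cell and endothelial markers higher, in 11 of 13, 14 of 14 and 21 of 23 genes (adjusted p = 0.00018, 0.028 and 0.038), and the control list of ribosomal proteins lower, in 20 of 25 genes with a median of -0.05 (adjusted p = 0.045). With an estimated correlation these had adjusted p = 0.3, 0.53, 0.76 and 0.53. The remaining lists called higher were cytokines and receptors, chemokine receptors, the TGF-beta pathway and myofibroblast and SRF or YAP target genes. In all, camera called 15 lists at day 6, 13 higher and 2 lower, and 0 with an estimated correlation or with fry, of 32 lists tested.

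The count of 10 genes depended on the processing. It was 306 after quantile normalization between arrays, 453 with array weights and 24 with only the day 6 arrays, and it was 6, 4, 3, 2 and 4 without unstressed replicates 1 and 4 and stressed replicates 1, 3 and 4 of day 6, while 1123 genes had an unadjusted p under 0.05.

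**Figure D1:**
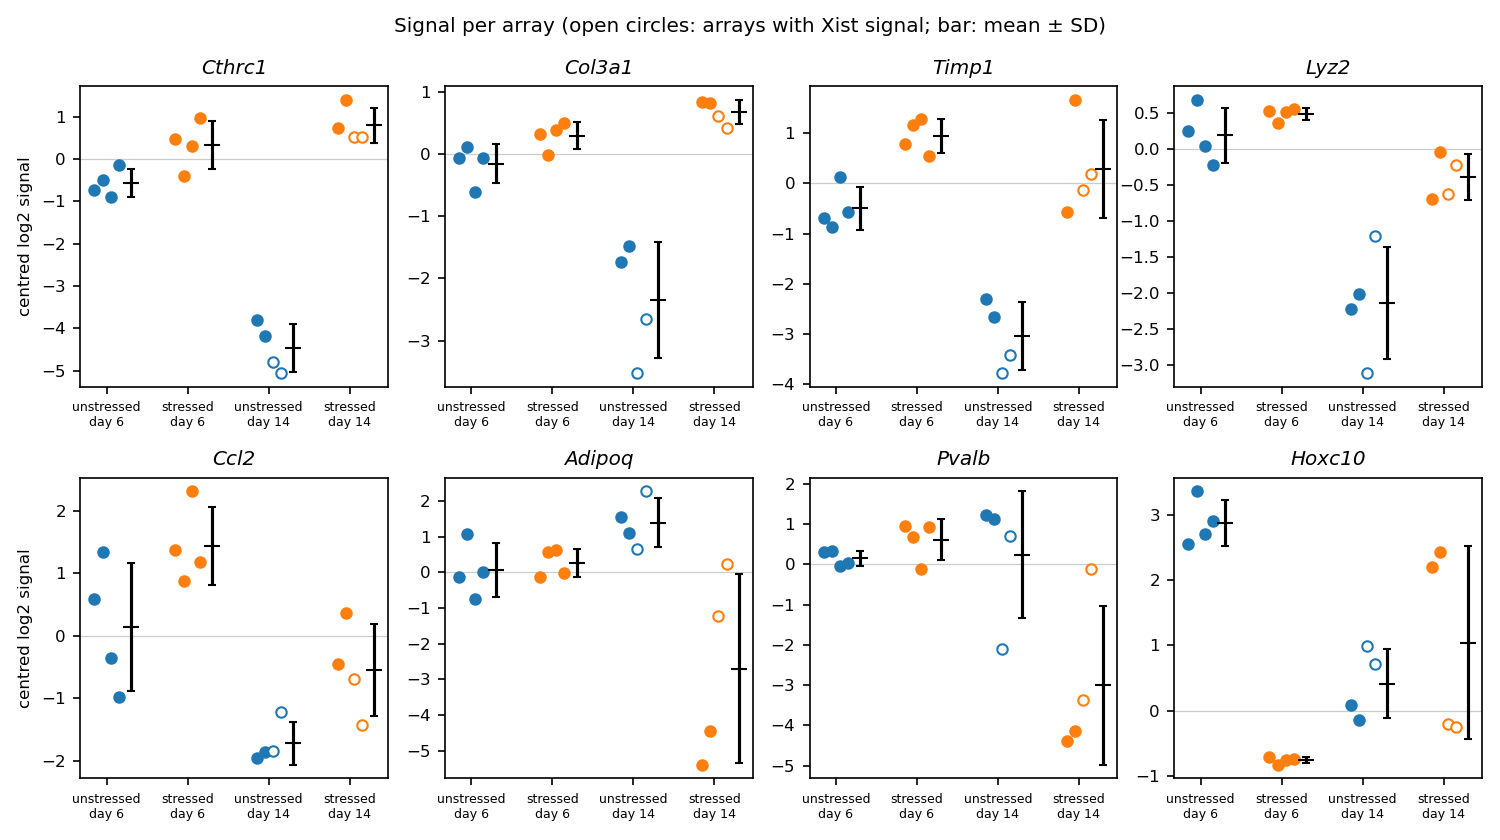
Centred log2 signal of 8 genes (vertical axes) in each of the 16 arrays, by group (horizontal axes), where points are arrays, open where Xist was high, and bars give the mean and SD of 4 arrays. Cthrc1 lay at -4.46 ± 0.57 in unstressed and 0.79 ± 0.42 in stressed wounds at day 14, and Hoxc10 at 2.89 ± 0.35 and -0.76 ± 0.05 at day 6.

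At day 14, matrix and myeloid transcripts were mostly higher and muscle and fat transcripts mostly lower in stressed wounds, by camera at its preset correlation and not with an estimated one. The muscle median was -3.53 in replicates 1 and 2 and -0.75 in replicates 3 and 4, and fry did not call that list (adjusted p = 0.052). Of 18193 genes, 706 rose and 777 fell in stressed wounds, 1483 in all, in the fit of all arrays, whose SE includes the spread at day 6. Of the 1483 genes, 712 differed at least 2-fold. With only the day 14 arrays 95 genes passed, 78 higher and 17 lower, and 433 higher and 259 lower with Xist as a block. In the fit of all arrays the counts were 857 higher and 570 lower without stressed replicate 3 of day 14. Without stressed replicate 4 they were 1086 and 1610, so the balance of directions is not settled. Among genes whose groups did not overlap, the largest rise was that of Cthrc1, a secreted protein with a collagen-like repeat (5.25, SE 0.31, adjusted p = 5.5e-07), which went from -4.46 ± 0.57 to 0.79 ± 0.42 (SD, n = 4). Next came Prss35, a serine protease-like protein (5.04), Aspn, the small leucine-rich proteoglycan asporin (4.85), the matricellular protein Ccn3 (4.55), the secreted Wnt modulator Sfrp2 (4.52), C1qtnf3 (4.07), the collagen gene Col8a1 (4.02) and Lrrc17 (3.91). The largest falls with no overlap between the groups were those of Apobec2 (-4.61, SE 0.49, adjusted p = 0.00012), the mitochondrial creatine kinase Ckmt2 (-4.42), adiponectin, Adipoq (-4.09), Timp4 (-3.68), Asb5 (-3.66), the B cell attractant Cxcl13 (-3.51), the muscle adenylosuccinate synthase Adssl1 (-3.45) and Retnla (-3.44). The second probe set of Apobec2 differed by 0.52, against the direction of the first.

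Of 39 matrix genes, 31 rose and 0 fell at day 14, and 32 rose when adjusted over the list alone, with a median of 1.80 (camera adjusted p = 1.6e-30, and adjusted p = 0.064 with an estimated correlation). Besides Cthrc1, Aspn and Col8a1, Col12a1 rose by 3.74 (SE 0.55, adjusted p = 0.0017) and Col3a1 by 3.02 (SE 0.33, adjusted p = 0.00015). For Col1a1 the 2 probe sets disagreed, at -0.90 for the more variable one (adjusted p = 0.25) and 1.66 for the other. Fibroblast markers rose in 5 of 16 genes, and in 9 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 3e-06, and adjusted p = 0.22 with an estimated correlation). They share Col1a1, Col1a2, Col3a1, Dcn and Lum with the matrix list. Of 28 matrix proteases and inhibitors, 16 rose and 1, Timp4, fell, with a median of 1.27 (camera adjusted p = 1.6e-11, and adjusted p = 0.086 with an estimated correlation); adjusted over the list alone the counts were 17 and 1. Adam12 rose by 3.86, the macrophage elastase Mmp12 by 3.79, the inhibitor Timp1 by 3.33 and the membrane-bound Mmp14 by 2.88. In the TGF-beta pathway list, 6 of 28 genes rose and 1 fell, and 8 and 1 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0087, and adjusted p = 0.25 with an estimated correlation). Those that rose included Bmp1, a procollagen proteinase (2.04, SE 0.38), Tgfb3 (1.79, SE 0.29) and the latent TGF-beta binding protein Ltbp2 (1.60, SE 0.37).

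Of 36 integrin and focal adhesion genes, 6 rose at day 14, and 7 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.01, and adjusted p = 0.46 with an estimated correlation). The integrin Itgav rose by 1.25 (SE 0.28, adjusted p = 0.014) and vinculin, Vcl, by 1.24 (SE 0.37, adjusted p = 0.049). Itgb1 was 1.19 higher (adjusted p = 0.041 in limma, and 0.07 with the replicate number as a block), and 5 of its 6 probe sets shared that direction. Acta2, the smooth muscle actin of myofibroblasts, differed by -0.08 (SE 0.46, adjusted p = 0.94).

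Macrophage and monocyte markers rose in 12 of 22 genes and fell in 1, and in 17 and 1 adjusted over the list alone, with a median of 1.18 (camera adjusted p = 2.4e-09, and adjusted p = 0.22 with an estimated correlation). Cd68 rose by 1.76 (SE 0.33), the lysozyme gene Lyz2 by 1.74 (SE 0.30), the Fc receptor Fcgr1 by 1.72 (SE 0.32) and the integrin Itgam by 1.54 (SE 0.39), while Retnla, a marker of alternatively activated macrophages, fell by 3.44 (SE 0.53). Of 15 neutrophil markers, 3 rose, and 4 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.00018, and adjusted p = 0.22 with an estimated correlation). S100a8 was 2.78 higher (SE 0.77, adjusted p = 0.038) and Clec4d 2.45 higher (SE 0.39, adjusted p = 0.0023). Among 37 cytokines and receptors 5 rose and 1 fell, and 9 and 1 adjusted over the list alone, led by the alarmin Il33 (2.87, SE 0.40) and the macrophage growth factor receptor Csf1r (1.45, SE 0.30), with a median of 0.41 (camera adjusted p = 0.0011, and adjusted p = 0.37 with an estimated correlation). Among 33 chemokines 2 rose and 1 fell over all genes. Ccl12 rose by 1.77 (SE 0.41, adjusted p = 0.017) and Cxcl13 fell. Ccl8 was 1.23 higher (adjusted p = 0.049 in limma, and 0.059 with the replicate number as a block), and Ccl2 1.17 higher (SE 0.46, adjusted p = 0.13). The chemokine list had a median of 0.39 and 4 higher and 1 lower genes adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.46 with an estimated correlation).

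Skeletal muscle markers fell in 18 of 32 genes and rose in 1, the troponin C gene Tnnc1 of slow and cardiac muscle (2.29, SE 0.66, adjusted p = 0.044), with a median of -2.15 (camera adjusted p = 2e-09, and adjusted p = 0.44 with an estimated correlation); adjusted over the list alone the counts were 24 and 3. Myot, a Z-disc protein, fell by 3.94 (SE 0.75), and the differences were -3.70 for the muscle glycogen phosphorylase Pygm (SE 0.68) and -3.25 for the calcium buffer Pvalb (SE 0.81). Adipocyte markers fell in 11 of 18 genes, and in 13 adjusted over the list alone, with a median of -1.64 (camera adjusted p = 1.1e-10, and adjusted p = 0.22 with an estimated correlation). They included Thrsp (-3.92, SE 0.86), the lipid droplet protein Cidec (-3.02, SE 0.62) and Plin4 (-2.76, SE 0.49). These muscle and adipocyte counts are of the fit of all arrays, whose SE includes the spread at day 6. With only the day 14 arrays 17 genes in all passed as lower, so not all of these falls hold there. With Xist as a block in those arrays the number was 259. Hair shaft and follicle genes were lower in 36 of 37 genes with a median of -0.77 (camera adjusted p = 0.0011, and adjusted p = 0.61 with an estimated correlation), and 2 of them passed over all genes and over the list alone. They were Sox9 (-1.39, SE 0.30, adjusted p = 0.013) and Lhx2 (-1.96, adjusted p = 0.039 in limma, and 0.075 with the replicate number as a block). Interferon response genes were higher in 23 of 24 genes with a median of 0.49 (camera adjusted p = 0.0011, and adjusted p = 0.5 with an estimated correlation). Of these Ddx58 alone passed, over all genes and over the list alone (0.63, adjusted p = 0.033 in limma, and 0.054 with the replicate number as a block). Endothelial markers were higher in 18 of 23 genes with a median of 0.59 and 0 past the threshold over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.61 with an estimated correlation). Camera called 16 lists at day 14, and fry 10.

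The day 14 arrays fell into 2 classes that did not follow loading. Although all 16 arrays are labelled female, replicates 3 and 4 of both groups of day 14 had a high signal of Xist, the transcript of the inactive X chromosome, at 5.98 to 6.30, and low signals of 3 Y-linked genes, whose means lay at -3.97 to -3.53. In the other 12 arrays, all of day 6 and replicates 1 and 2 of both groups of day 14, Xist lay at -0.53 to 0.81 and the Y-linked mean at -0.99 to 0.74. Low Xist with higher Y-linked signal goes against the label female for these 12 arrays. Whether the label or the identity of the samples is wrong was not tested. In replicates 1 and 2, the median difference between stressed and unstressed wounds was 1.68 for matrix genes, 1.23 for macrophage markers, -2.14 for adipocyte markers and -3.53 for muscle markers. In replicates 3 and 4 these were 2.13, 0.99, -0.99 and -0.75. With only the Xist arrays at day 14 the muscle, TGF-beta, chemokine and interferon lists were not called by camera (adjusted p = 0.15, 0.13, 0.46 and 0.067), and with only the Y-signal arrays endothelial markers were not (adjusted p = 0.13). The classes were balanced over the loading groups, so the medians with Xist as a block were equal to those of all arrays (1.80, 1.18, -1.64 and -2.15). The median of the chemokine list was 0.54 in replicates 1 and 2 and 0.10 in replicates 3 and 4. The count of 1483 genes became 2232 with Xist as a block, 692 in the 8 day 14 arrays with that block, 3393 with only the Y-signal arrays and 485 with only the Xist arrays at day 14. It was 95 with only the day 14 arrays, 263 after quantile normalization, 2726 with array weights, and 844, 621 and 2696 without stressed replicates 1, 2 and 4 of day 14.

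**Figure D2:**
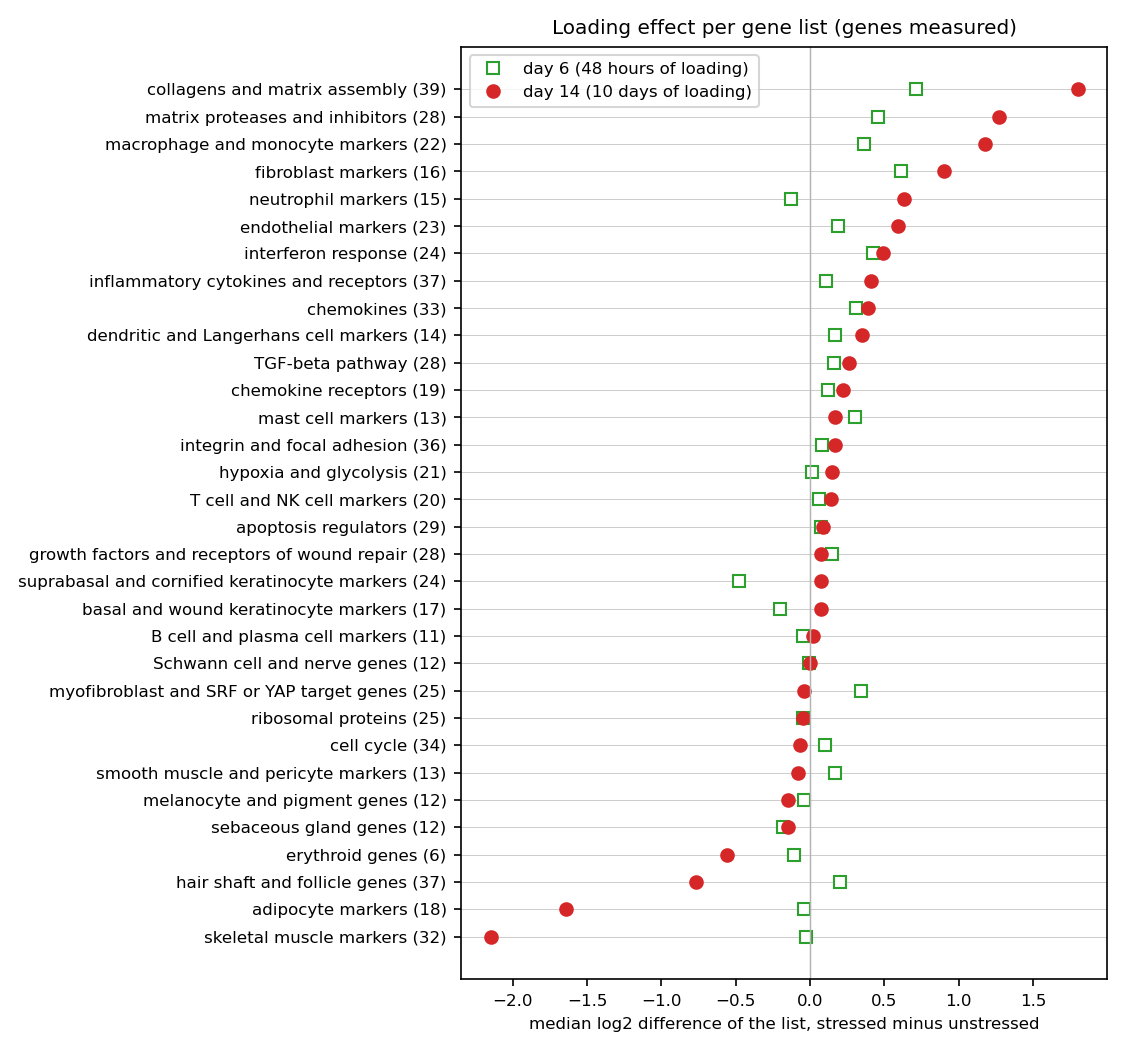
Median log2 difference, stressed minus unstressed (horizontal axis), of each of the 32 gene lists (vertical axis, with the number of genes measured), at day 6 (open squares) and day 14 (filled circles). Matrix genes had a median of 0.71 at day 6 and 1.80 at day 14, and skeletal muscle markers lay at -0.03 and -2.15.

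The test of the difference between the loading effects of the 2 days asked which genes responded otherwise at day 14 than at day 6. In limma 7 genes passed. The loading effect was more positive at day 14 for Cthrc1 (4.35, SE 0.44, adjusted p = 0.00099), the collagen gene Col5a2 (2.47, SE 0.40), the protease gene Ctss (2.16, SE 0.35) and periostin, Postn (1.61, SE 0.26). It was more negative for Apobec2 (-4.78, SE 0.69), Timp4 (-3.71, SE 0.61) and the kinase gene Prkg2 (-3.31, SE 0.46). With the replicate number as a block within each day, the count was 19, and Ctss (adjusted p = 0.055) and Postn (adjusted p = 0.065) did not pass. With the number as a block over all arrays the count was 4, and Col5a2, Ctss, Postn and Timp4 did not pass (adjusted p = 0.07 to 0.071). Camera called 9 lists, 6 more positive and 3 more negative at day 14, and 0 with an estimated correlation or with fry. Matrix genes had a median of 1.28 (camera adjusted p = 8.3e-17, and adjusted p = 0.26 with an estimated correlation). In that list 3 of 39 genes were more positive at day 14 over all genes and 18 adjusted over the list alone. Muscle markers had a median of -2.06 (camera adjusted p = 9.7e-11, and adjusted p = 0.69 with an estimated correlation). Of the 32 muscle markers 0 passed over all genes, and 20 were more negative adjusted over the list alone. High Xist occurred only at day 14, and the count was 52 with Xist as a block, 1418 with only the Y-signal arrays, 191 without stressed replicate 4 of day 14, 61 without unstressed replicate 3 of day 14 and 1 to 11 without any other array that moved it by more than 1.5 times. Across the 18193 genes, which are not independent replicates, the loading effects of the 2 days had a Pearson correlation of 0.36 and a Spearman correlation of 0.34 with no shared arrays, and 4 genes were called in the same direction at both days against 0.40 expected for independent lists. Both tests use the same estimate of each gene's spread, so the lists of calls are not independent. The overlap alone therefore does not show a shared effect.

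Between day 6 and day 14, hair follicle transcripts were mostly higher in unstressed wounds. Those of interferon response, macrophages, matrix and cornifying epidermis were mostly lower. These are calls by camera at its preset correlation and not with an estimated one. Array preparation also differed between the days, as given below, and could not be told apart from day. In limma 4211 genes rose and 5794 fell. A gene's probe set was chosen by its interquartile range over all 16 arrays, which includes the difference between days and can favour these calls. With the mean of a gene's probe sets 3314 genes rose and 4671 fell. Hair shaft and follicle genes rose in 32 of 37 genes, and in 32 adjusted over the list alone, with a median of 4.92 (camera adjusted p = 7.3e-13, and adjusted p = 0.72 with an estimated correlation). The keratin-associated proteins Krtap8-1 (7.84, SE 0.88) and Krtap11-1 (7.01, SE 1.14) and the hair keratins Krt26 (6.94, SE 1.01) and Krt33a (6.91, SE 1.10) rose most among them. Pigment genes rose in 6 of 12 genes, including Trpm1 (2.73) and Oca2 (1.86), with the same count adjusted over the list alone and a median of 1.06 (camera adjusted p = 0.021, and adjusted p = 0.78 with an estimated correlation). Interferon response genes fell in 21 of 24 genes, and in 22 adjusted over the list alone, with a median of -1.87, Ifit1 at -2.89 and Irf7 at -2.53 (camera adjusted p = 4.7e-07, and adjusted p = 0.72 with an estimated correlation). Macrophage markers fell in 16 of 22 genes and rose in 2, with the same counts adjusted over the list alone and a median of -1.89 (camera adjusted p = 7.9e-05, and adjusted p = 0.75 with an estimated correlation), Fcgr1 by 3.73 and Cd68 by 2.92. Matrix genes fell in 28 of 39 genes and rose in 2, and in 29 and 2 adjusted over the list alone, with a median of -1.35 (camera adjusted p = 0.00012, and adjusted p = 0.75 with an estimated correlation), Cthrc1 at -3.89 and Col1a2 at -3.04. Suprabasal keratinocyte markers fell in 20 of 24 genes, also when adjusted over the list alone, including the kallikrein Klk5 (-3.24) and hornerin, Hrnr (-3.20), with a median of -1.66 (camera adjusted p = 0.00023, and adjusted p = 0.72 with an estimated correlation). Other large falls were those of Serpinb12 (-6.28), Rnase2b (-6.06) and the collagenase Mmp13 (-4.73).

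In stressed wounds 4363 genes rose and 6241 fell between the days, and 3386 rose and 4915 fell with the mean of a gene's probe sets. Hair shaft and follicle genes rose in 29 of 37 genes and fell in 1, and in 30 and 1 adjusted over the list alone, with a median of 3.43 (camera adjusted p = 1.3e-07, and adjusted p = 0.98 with an estimated correlation), and Krtap8-1 rose by 6.99 (SE 0.88). Interferon response genes fell in 21 of 24 genes, also when adjusted over the list alone, with a median of -1.84 (camera adjusted p = 3.6e-06, and adjusted p = 0.98 with an estimated correlation). Skeletal muscle markers fell in 29 of 32 genes, and in 30 adjusted over the list alone, with a median of -2.78 (camera adjusted p = 1e-05, and adjusted p = 0.98 with an estimated correlation), including the myosin heavy chains Myh4 (-4.92, SE 1.14), Myh8 (-3.77, SE 0.98) and Myh3 (-3.65, SE 0.71). Macrophage markers fell in 16 of 22 genes and rose in 1, and in 17 and 1 adjusted over the list alone (median -1.07, camera adjusted p = 0.011, and adjusted p = 0.98 with an estimated correlation). Of 33 chemokines 18 fell and 2 rose, also when adjusted over the list alone, with a median of -0.95. Camera did not call them (adjusted p = 0.11). In unstressed wounds 15 fell and 2 rose, also when adjusted over the list alone, with a median of -0.62 and no call by camera (adjusted p = 0.16). Among those that fell in stressed wounds were Cxcl2 (-2.63), Cxcl10 (-2.46) and Ccl2 (-1.99, SE 0.46, adjusted p = 0.0021). Defb8 fell by 5.15 (SE 0.59), from 4.60 ± 1.81 to -0.55 ± 0.12 (SD, n = 4). Matrix genes were called higher in 2 and lower in 6 of 39 genes, and in 2 and 4 adjusted over the list alone. Their median lay near 0, and camera did not call them (adjusted p = 0.76).

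Day and array preparation could not be told apart in these time comparisons. The 12 probe sets of the poly-A controls, bacterial transcripts that are spiked into the RNA before labelling, averaged 0.66 ± 1.47 at day 6 and -5.02 ± 0.09 at day 14 (SD, n = 8 per day; exact permutation test, two-sided p = 1.6e-04). The median difference of all genes between the days was -0.09 in unstressed and -0.14 in stressed wounds.

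**Figure D3:**
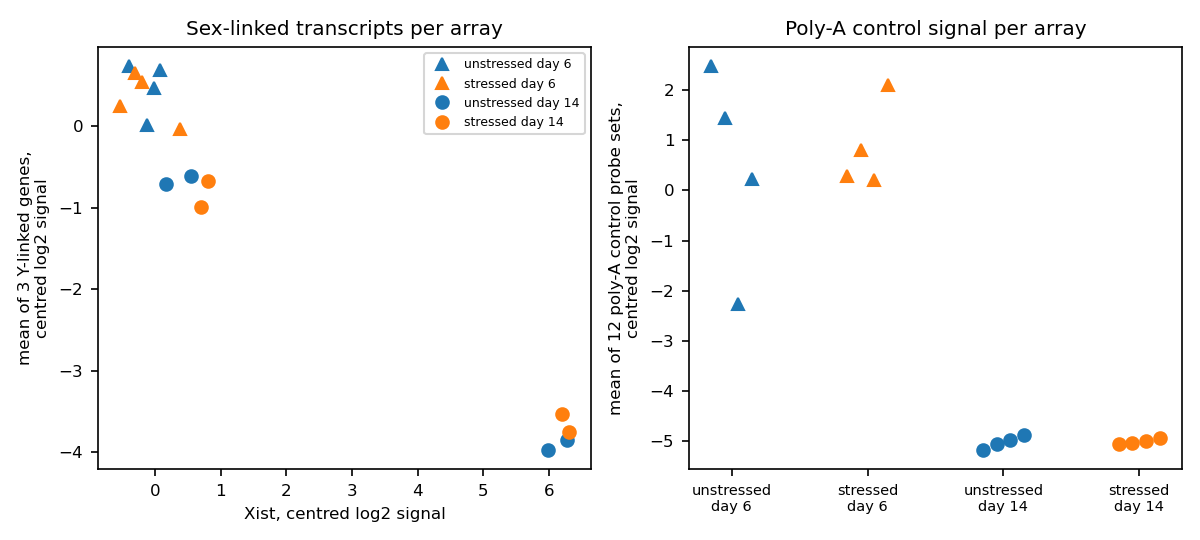
Left, mean of 3 Y-linked genes against Xist for each array, both as centred log2 signal; right, mean of 12 poly-A control probe sets per array (vertical axis, centred log2 signal) by group. The 4 arrays with Xist lie at 5.98 to 6.30 on the horizontal axis, and the poly-A controls at day 14 average -5.02.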

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

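All tests of explanations and all counts of other splits of the arrays in this part were chosen after the results they bear on were seen.

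The rise of matrix genes with the fall of muscle and fat genes in stressed wounds at day 14 could come from a smaller share of muscle and fat RNA, which would raise all other transcripts alike. The tables argue against that as the whole cause, since the matrix median exceeded the median of 109 markers of endothelial cells, keratinocytes, T and NK cells, mast cells and Schwann cells (0.19) by 1.61 (95% bootstrap interval over genes 1.26 to 1.98), and the same difference per array was 0.57 ± 0.23 in stressed and -0.98 ± 0.37 in unstressed wounds (SD, n = 4, no overlap; exact permutation test within the 4 pairs of same-numbered arrays, two-sided p = 0.125, the smallest these pairs can give). The bootstrap treats genes as independent, although the estimated correlation within the matrix list was 0.30. Its interval is therefore too narrow and leaves out the spread between arrays, so the argument rests on the values per array. Macrophage (median 1.18) and neutrophil markers (0.63), not among the 109, were higher too. RNA quality as the whole cause was checked only through the 5' minus 3' difference of control genes. With it as a covariate 30 of 39 matrix genes still rose. That argues against the part of RNA quality that this difference measures. It lay furthest from 0 in stressed replicate 2 of day 6 (-1.51) and unstressed replicate 4 of day 14 (-0.85), so the check rests largely on these arrays. Whether less muscle in the sampled tissue sets the size of the matrix rise stays open: the median over the matrix genes of each gene's difference in replicates 1 and 2 minus that in replicates 3 and 4 was -0.41, and -2.75 over the muscle genes, but the mean matrix differences of the pairs of arrays ranged from 1.47 to 2.07 and from 1.70 to 2.51. A change in the cells that make matrix was not tested. The 8 splits that part all 4 same-numbered pairs of day 14 arrays are too few for a share under 0.05. The real one (1 split) gave 1483 genes and the highest other 525. The split of replicates 1 and 2 from 3 and 4, which follows the Xist classes, gave 593.

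Of 33 Hox genes, 14 were lower in stressed wounds at day 6, 22 lay within 0.25 of 0, and 2, Hoxc10 and Hoxa7, passed limma's threshold, both lower. Hoxa9 (2.56 ± 0.26 in unstressed and -0.44 ± 0.39 in stressed wounds, SD, n = 4; SE of the difference 0.74, adjusted p = 0.26), Hoxa10 (-1.24, adjusted p = 0.46) and Hoxb9 (-0.79, adjusted p = 0.38) were also lower but did not pass in the fit of all arrays, whose SE includes the spread at day 14. With only the day 6 arrays Hoxa9 (SE 0.21, adjusted p = 0.00063), Hoxa10 (adjusted p = 0.042) and Hoxa5 (adjusted p = 0.047) passed, and Hoxb9 did not (adjusted p = 0.1). With day 14 arrays of 1 Xist class, Hoxa9 passed with either class (adjusted p = 4.2e-05 with only the Y-signal arrays and 0.00011 with only the Xist arrays) and Hoxa10 with neither (0.073 and 0.076), while Hoxa5 passed with the Y-signal arrays (0.047) and not with the Xist arrays (0.082). RNA quality, as far as the 5' minus 3' difference measures it, is argued against as the whole cause for Hoxc10 by the fit with that covariate, where Hoxc10 differed by -3.52 (limma adjusted p = 0.021). Whether loading lowers Hoxc10 at both days stays open. At day 14 stressed minus unstressed was 2.35 in replicates 1 and 2 and -1.09 in replicates 3 and 4, but of the 7 other Hox genes lower by more than 0.5 at day 6, 5 changed sign in the same way (Hoxa9, 2.91 and -2.63; Hoxa10, 1.44 and -0.62; Hoxb9, 1.13 and -0.20; Hoxc9, 0.78 and -0.34; Hoxa7, 0.58 and -0.25). The other 2, Hoxa5 (-0.77 and -1.69) and Hoxb6 (-1.23 and -0.49), were lower in both. Hox genes mark position along the body, but the labels give no position of the wounds, so a difference in position was not tested and stays open beside an effect of loading at day 6. Of the 35 splits of the day 6 arrays only the real one (1 split) gave as many as 10 genes, with 2 as the highest other. That share, 2.86%, is the smallest that 35 splits can give, so chance is argued against but not excluded for the count. The count was 2 without stressed replicate 3 of day 6.

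The many genes that differ between days could reflect the 4 day 14 arrays with high Xist or a labelling batch. With only the 12 arrays with Y-linked signal, 9045 genes passed in unstressed wounds, 8011 of them among the 10005, so the Xist arrays are argued against as the whole cause. The poly-A controls, data outside the comparisons, differed by -5.68 between day 14 and day 6, with no overlap of the days (lowest at day 6 -2.26, highest at day 14 -4.89), so day and labelling batch cannot be told apart. Of 35 splits each, only the real one (1 split) gave as many genes in unstressed (10005, highest other 6) and in stressed wounds (10604, highest other 605). A split that mixes the days adds their difference to the spread, which lowers its count, and 1 of 35 is the smallest share possible. Chance is thus argued against but not excluded, and a batch that follows the days is left open.

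The loading effect differed between the days for 7 genes in limma, Cthrc1 (4.35), Col5a2 (2.47), Ctss (2.16), Postn (1.61), Prkg2 (-3.31), Timp4 (-3.71) and Apobec2 (-4.78). Of 100 splits that part all 4 day 14 pairs, the real one and 99 drawn, 16 gave as many genes, the real one included, with 329 as the highest other, so chance is not excluded for that count. The 11 drawn splits that kept the loading groups of day 14 and split day 6 otherwise gave 8 to 329 genes, and their contrast holds the day 14 loading effect. Of the 87 that split both days otherwise 4 gave as many, with 18 as the highest. By camera 9 lists differed between the days, with medians of 1.28 for matrix genes, 0.88 for matrix proteases and inhibitors, 0.80 for macrophage and monocyte markers, 0.78 for neutrophil markers, 0.60 for suprabasal keratinocyte markers, 0.44 for fibroblast markers, -1.12 for hair genes, -1.51 for adipocyte markers and -2.06 for skeletal muscle markers. With an estimated correlation 0 of the 32 lists were called (lowest adjusted p = 0.26), and 0 with fry.

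In 331 combinations of a named gene and a group, and in control measures of each group beside them, 19 cases had 1 array far from the other 3. Of these, 1 was a control measure. Chance gives about 1 in 20 if genes are independent, which muscle genes of 1 array need not be, so the number of cases is near that share. In unstressed wounds at day 14, replicate 3 lay below the others in Ckmt2 (-0.90 against a mean of 1.91), Adssl1 (-0.94 against 1.32), Myot (-0.27 against 1.51), Pvalb (-2.09 against 1.03) and Eno3 (-1.39 against 1.03), all genes of muscle (without this array the median of the muscle list at day 14 was -2.54, against -2.15), replicate 1 lay above in Egfl7 (-0.27 against -0.82), and replicate 4 stood apart in Ccl2 (-1.22 against -1.89), Tnnt2 (-4.77 against -4.44) and Bid (-0.84 against -1.41). In stressed wounds at day 14, replicate 4 lay above the others in Ckmt2 (-1.25 against -3.87), Timp4 (-0.72 against -1.29) and Cidec (0.70 against -2.35), replicate 1 below in Sfrp2 (-0.66 against 1.69), replicate 2 above in Itgb1 (1.45 against 0.38) and replicate 3 below in Cxcl10 (-1.86 against -1.52). At day 6, unstressed replicate 2 lay below the others in P4ha3 (-0.97 against -0.23), unstressed replicate 3 in Dcn (-0.57 against -0.30) and Gpr143 (-0.65 against -0.03), and stressed replicate 2 in the 5' minus 3' difference of control genes (-1.51 against 0.06).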

How the results depend on the processing

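The settings with Xist as a block, with arrays of 1 Xist class only, without 3 arrays with low 5' signal and with the 5' minus 3' covariate were chosen after the data were seen. The log2 differences of genes named by the rule, each by its most variable probe set or the mean of its probe sets, kept their direction under all settings run, except 12 results of Col1a1 and Acta2; other probe sets of a gene could differ in direction, as those of Apobec2 did. Of the named genes' results under other settings, 1155 of 1269 for loading at day 6, 1712 of 2014 at day 14, 99 of 210 for the difference between days, 1234 of 1240 and 955 of 961 for time in unstressed and stressed wounds stayed on their side of the threshold. Of the described lists' results 217 of 231, 438 of 476, 217 of 231 and 155 of 165 did so for loading at day 6, at day 14 and time in unstressed and stressed wounds. For loading at day 6 the count of 10 genes became 306 after quantile normalization, 24 with only the 2 groups, 453 with array weights, 31 with only the Y-signal arrays, 18 with only the Xist arrays at day 14, and 2 to 13 without 1 array. The 24 calls with only the 2 groups held 7 of the 10 genes, while the 306 and the 453 held all 10. For day 14 the count of 1483 became 263 after quantile normalization, 95 with only the 2 groups (82.1% of them higher against 47.6%), 2726 with array weights, 712 at 2-fold or more (391 higher and 321 lower), 2232 with Xist as a block, 3393 with only the Y-signal arrays, 485 with only the Xist arrays, 692 in the 8 day 14 arrays with Xist as a block, and 621 to 2696 without 1 array. Without the 3 arrays with low 5' signal it was 1464 (909 higher and 555 lower), 941 of them among the 1483. Of the 485 calls with only the Xist arrays 277 were among the 1483, as were 94 of the 95 with only the 2 groups. For the difference between days the count of 7 became 20 without the lowest 40% of genes by interquartile range, 1 with the mean of probe sets, 3 with each probe set tested, 3 with trend and robust options, 569 with array weights, 52 with Xist as a block, 1418 with only the Y-signal arrays, 40 with only the Xist arrays, 2 without the arrays with low 5' signal, 1 with the covariate, and 1 to 191 without 1 array; after quantile normalization 2 of 5 calls were higher against 4 of 7. Of the 7 genes, 1 was among the 5 calls after quantile normalization and 2 were among the 40 with only the Xist arrays. All 7 were called with array weights, with Xist as a block and with only the Y-signal arrays. The time counts became 3154 (778 higher and 2376 lower) and 3299 (832 higher and 2467 lower) at 2-fold or more in unstressed and stressed wounds, and lay at 8570 to 10206 and 9188 to 10842 without 1 array. Camera with an estimated correlation called 0 lists in each of the 5 comparisons, and fry called 0 at day 6, 10 at day 14, 0 for the difference between days, and 19 and 14 for time in unstressed and stressed wounds. For time in unstressed wounds 5 lists were called after quantile normalization and 6 with Xist as a block, and in stressed wounds 3 with Xist as a block and 9 with only the Xist arrays. Without 1 array the called lists numbered 10 to 18, 11 to 17, 7 to 12, 8 to 12 and 4 to 6 in the 5 comparisons, and the correlation between the days' loading effects was 0.297 to 0.417. With the replicate number as a block within each day, the day 6 count was 1 and that of the difference 19, and with the number as a block over all arrays the difference count was 4; day 6 numbers do not pair the arrays. At day 14, where the deviations of same-numbered arrays correlated but a pairing beyond the Xist class is not shown, the block within the day gave 1341 genes, 1092 of them among the 1483. It ended the limma calls of Cxcr2 (adjusted p = 0.051), Ccl8, Itgb1, Ddx58, Casp8 (0.07) and Lhx2, and no other of 77 named results. Col1a1 at day 6 (-0.02) was 0.22 after quantile normalization and 0.08 with the mean of probe sets, and 0.30, 0.08, 0.03 and 0.12 without unstressed replicate 3 and stressed replicates 1, 3 and 4, in a range of -0.32 to 0.30 without 1 array. Acta2 at day 14 (-0.08) was 0.49 with only the Xist arrays, and 0.13, 0.19, 0.29 and 0.08 without unstressed replicates 1 and 2 and stressed replicates 1 and 3, in a range of -0.54 to 0.29 without 1 array. Col1a1 at day 14 (-0.90) was 0.38 with the mean of probe sets, since its 2 probe sets differ in sign. The cause of the other changes was not tested. Quantile normalization assumes equal distributions, which a centred table with a narrower spread at day 6 need not have, and adding 16 before the log was not run on centred values. Signal over background could not be judged.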

Other observations

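Except for genes that the rule also named, among them Cxcr2, Casp8 and Bcl2l11, the genes in this part were chosen after their values were seen. All tests here are limma's or camera's of the report. At day 14, 3 of 14 dendritic and Langerhans cell markers rose in stressed wounds, the integrin Itgax (1.45, SE 0.27) and the class II histocompatibility genes H2-Ab1 (1.86, SE 0.43) and H2-Eb1 (1.01, SE 0.30), with the same count adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.46 with an estimated correlation). Of 19 chemokine receptors 3 rose, Ccr1 (2.33, SE 0.36), Ccr2 (1.31, SE 0.38) and Cxcr2 (0.63, SE 0.19), again also adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.34 with an estimated correlation). Growth factors and receptors of wound repair moved both ways, with Igf1 (2.32, SE 0.42) and Pdgfd (2.12, SE 0.45) higher and Ereg (-1.54, SE 0.35), Met (-0.96, SE 0.22) and Igf1r (-0.67, SE 0.18) lower, and camera did not call the list (adjusted p = 0.7). Myofibroblast and SRF or YAP target genes also moved both ways: Cdh11 (3.25, SE 0.42) and Cald1 (1.11, SE 0.32) rose, and the tropomyosin genes Tpm1 (-2.09, SE 0.42) and Tpm2 (-2.55, SE 0.50) fell (camera adjusted p = 0.89). Tropomyosins are also made in skeletal muscle, whose markers had a median of -2.15. Apoptosis regulators had 3 genes that rose and 1 that fell of 29, and 5 and 1 adjusted over the list alone, with Bcl2l11 at 1.38, Casp8 at 0.98, Apaf1 at 0.66 and Mcl1 at -0.83, and no call by camera (adjusted p = 0.074). With the replicate number as a block within the day, Cxcr2 (adjusted p = 0.051), Igf1r (0.062) and Casp8 (0.07) did not pass over all genes, and with the number as a block over all arrays Igf1r (0.055), Ccr2 (0.056), H2-Eb1 (0.063), Bcl2l11 (0.064) and Casp8 (0.068) did not.

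At day 14 the median loading effect on cell cycle genes was -0.73 in replicates 1 and 2, where 4 of 34 genes were positive, and 0.67 in replicates 3 and 4, where 32 were positive, while over all arrays the median was -0.07 (camera adjusted p = 0.89). For 12 melanocyte and pigment genes the medians were -1.06 and 0.84. The difference of the loading effect between the 2 pairs of replicates was not tested, so neither list is shown to differ between them.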
